A study of Mus musculus with 6 samples.

How the data were processed

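Cap-enriched RNA from the livers of male mice aged 2 months was sequenced in 6 libraries, 3 from wild-type animals and 3 from animals labelled as knockouts of SHP, the orphan nuclear receptor encoded by Nr0b2. Per the labels' protocols, TRIzol-extracted RNA was enriched for 5′ caps with a high-affinity variant of the cap-binding protein EIF4E, barcoded with the Illumina protocol and read from both ends for 36 cycles, with 3 barcoded samples in each lane. Which samples shared a lane is not given in the sources used here, so lane and genotype cannot be told apart. Because the selection acts on capped RNA, values were not read as those of total RNA. Some uncapped RNA was also sequenced: mitochondrially encoded genes, whose transcripts carry no such cap, took 5.66% to 10.3% of counts per library.

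Reads were aligned with Novoalign 2.05.33 to mm9, per the submitters' processing notes. The counting tool, its treatment of reads with several alignments or of strand, and the annotation release are not given in the sources used here. The authors deposited raw whole-number read counts per Ensembl gene and library, with RPKM values and a log2 ratio for the pooled groups. The RPKM values and the log2 ratio pool the 3 libraries of a group, so they carry no replicate error. The authors also deposited 2 columns of scores, a negative binomial p and its Benjamini-Hochberg adjusted value. Benjamini-Hochberg adjustment of the p scores, read as −10 times the log10 of p, gave a median ratio of 1 to the deposited adjusted scores, so both were read on that scale. The RPKM denominators matched the totals of 26465203 wild-type and 25897835 knockout observations per the file headers, of which 64.0% and 65.0% lay in genes.

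The table listed 33495 genes, of which 19594 had counts and 13901 had empty cells, among them 4840 whose lines ended early. Genes with empty cells were left out of library totals and tests. Every measured count was whole and at least 0. The early line ends were also why these columns were recorded under a general unit and not as counts: an automated check of units reads the missing cells as text. As a consequence the planned main test, edgeR's quasi-likelihood model, was not run, and neither were its robust form and DESeq2. The limma voom test, chosen as an alternative before the data were examined, took the place of the main test. The planned test on RPKM values per sample was not run either, because RPKM is deposited only for pooled groups. Even numbers made up 61.8% of counts from 1 to 19, as happens where both mates of a pair are often counted, so counts are not independent fragments. Start coordinates, which count from 0 in the table, were raised by 1. Gene symbols are those of the table. Current names for 18248 of the Ensembl identifiers came from a later annotation, which was used for names only.

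Library totals over genes were 5798186, 4982530 and 6155064 counts in wild type and 4494353, 5109217 and 7225842 in knockout. A gene was tested when at least 3 libraries reached 1.83 CPM (a count relative to the library total), which is 10 counts at the median library size, and its total reached 15 counts. This left 11794 genes. Library sizes were scaled by trimmed means of M values with code written for this work, giving factors from 0.966 to 1.03. CPM in the text are on these scaled sizes. Precision-weighted log2 CPM, with 0.5 added to each count, were fitted with limma 3.58.1 (voom, lmFit, eBayes) in R 4.3.3, with genotype as the only term. A gene passed the threshold at a Benjamini-Hochberg adjusted p under 0.05. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and draw the plots.

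Before the data were examined, 33 gene lists were fixed, covering bile acid, sterol, lipid, glucose and xenobiotic metabolism, stress and inflammation, and markers of liver zones and of other cell types. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry were alternatives. Neither the labels nor the table say that equal replicate numbers mark a shared litter, day or lane. The rule for named genes was also fixed beforehand. It takes Nr0b2, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and an approved-looking symbol, 14 further fixed names, and up to 4 passing and 2 other members of each list. After the data were seen it was narrowed, for length, to the first 3 passing members and 1 other member of each list past the threshold and the first 2 passing members of the remaining lists, not all of which are named. Some genes that the rule names are not reported here. Npas2, a fixed name, was below the filter and was not tested. Genes with near-identical copies, among them members of the Cyp2 and Cyp4 clusters and Orm genes, may have had their reads split and are uncertain.

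Counts for the 11794 genes were simulated independently, with 200 genes changed and the same dispersion of 0.0104 for every gene. The same fit recovered 92.0% of genes raised 2-fold and 100% of those raised 4-fold. It recovered 80.0% of those lowered to 0.5 of their level and 98.0% of those lowered to 0.25. Real genes differ in dispersion and both mates of a pair may be counted, so recovery in the real data may differ. In the simulation the fit made 11 false calls among 196. Alternatives were other scalings, no filter and a stricter filter, the replicate number as a block, leaving out each library in turn, and other windows around Nr0b2. After the data were seen, limma trend without precision weights, robust variance moderation and a fit without mitochondrially encoded genes were added. Counts per list at an unadjusted p, simulated recovery by level and the test of genes 2 to 20 Mb from Nr0b2 without each library were added last, also after the data were seen. The labels tell the samples of a group apart only by number, and p-values measure the spread between these samples.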

Results

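The study compared cap-enriched liver RNA of 3 SHP-knockout and 3 wild-type male mice of a C57BL6 background, aged 2 months, and asks which transcripts differ between them. SHP, encoded by Nr0b2, is a nuclear receptor without a DNA-binding domain that represses other transcription factors and takes part in the feedback on bile acid synthesis. Totals ran from 4494353 to 7225842 counts per library. Mitochondrially encoded genes took 10.2% ± 0.0616 (SD, n = 3) of wild-type counts and 6.50% ± 0.753 (SD, n = 3) of knockout counts. The groups did not overlap in this share, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Most of the share came from AY172335.7, which alone took 9.05% to 9.43% of wild-type and 5.07% to 6.39% of knockout counts. Libraries of one group differed by more than counting noise, so no library was a copy of another.

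Nr0b2 transcripts (ENSMUSG00000037583; mm9 chromosome 4, 133109291 to 133112451) were lower in the knockout libraries but still present. Their level was 14.5 ± 2.88 CPM in wild type and 8.04 ± 2.04 CPM in knockout (SD, n = 3 each). The 3 wild-type libraries held 104, 59 and 85 counts and the knockout libraries 29, 36 and 77. The log2 difference was −0.81 ± 0.25 (SE; limma voom, adjusted p = 0.0443), and every knockout library lay below every wild-type library. Groups of 3 fail to overlap by chance for 10% of genes, and did so for 4140 (35.1%) of the genes tested. In the authors' deposited table the log2 ratio of Nr0b2 was −0.84. Counts per gene do not show where in the gene the remaining reads lie, so they cannot tell a transcript of the altered allele from an intact one. The call was lost in 5 of the 6 fits that left out 1 library (adjusted p up to 0.124), and was kept only without knockout library 3, where the log2 difference was −1.06.

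Of 11794 genes tested, 1713 passed the threshold, with 894 higher and 819 lower in knockout liver. Changes of at least 2-fold were called for 235 genes that rose and 141 that fell, and for 192 genes in all without wild-type library 3. Meg3, a maternally expressed long non-coding RNA, had the largest increase among genes meeting the naming rule, from 3.25 ± 2.34 to 294 ± 52.8 CPM (log2 difference 6.75 ± 0.51, adjusted p = 1.08e-05). Asns, which makes asparagine, rose from 2.54 ± 1.12 to 105 ± 31.7 CPM (5.41 ± 0.50, adjusted p = 5.00e-05). The remaining large increases were in Cish and Socs3, which restrain cytokine signalling, in Gadd45g and Phlda1, and in Extl1, Mmd2, Srgap3 and Smoc2, with log2 differences from 2.59 for Smoc2 to 3.73 for Cish. Extl1 lies at chromosome 4, 133912287 to 133939765, close to Nr0b2.

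Among genes meeting the naming rule, the largest decreases were in Ppp1r3g, a glycogen-targeting phosphatase subunit, and Cib3, with log2 differences of −4.10 ± 0.92 (adjusted p = 0.0105) and −4.02 ± 0.74 (adjusted p = 0.00371). Pparg, a nuclear receptor of lipid storage, fell from 9.05 ± 3.79 to 1.23 ± 0.881 CPM (−2.86 ± 0.64, adjusted p = 0.00998). Slc10a2, the apical sodium-dependent bile acid transporter, fell from 16.8 ± 2.17 to 5.60 ± 4.81 CPM (−2.07 ± 0.42, and −1.28 without knockout library 3). Cyp2c55, Pdgfrl, Serpina12, Arl4d, Zfp750 and Tsc22d1 fell with log2 differences from −2.65 for Cyp2c55 to −1.67 for Tsc22d1; that of Pdgfrl was −1.94, and −1.26 without knockout library 3. The count of genes past the threshold was 620 without wild-type library 3 and 1066 without knockout library 1, and the calls of Ppp1r3g and Zfp750 were lost without wild-type library 3 (adjusted p = 0.0506 and 0.0539). Cish, Socs3, Gadd45g and Phlda1 lost their calls under robust variance moderation (adjusted p = 0.0653, 0.0935, 0.103 and 0.105), and wild-type library 1 was the highest wild-type library for each of them.

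**Figure D1:**
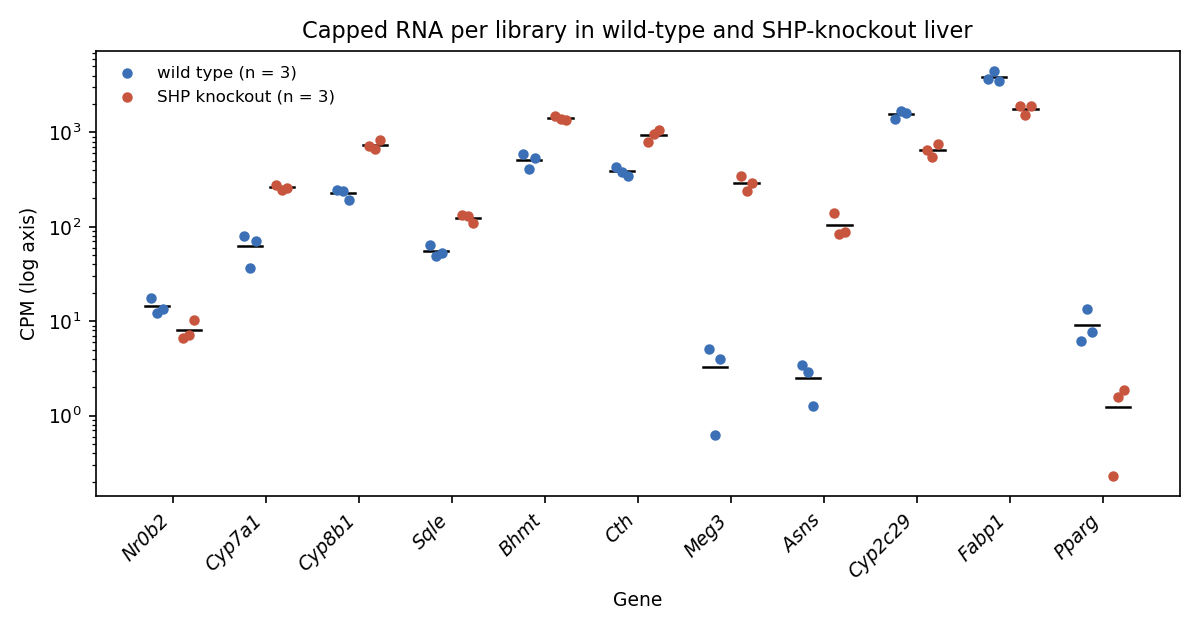
CPM (log axis) of 11 named genes in each library, with points for the 3 wild-type and 3 knockout libraries and a black line at each group mean. Meg3 lies at 3.25 CPM on average in wild type and 294 CPM in knockout, and Nr0b2 at 14.5 and 8.04 CPM.

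Transcripts of the 2 enzymes that set the amount and the kind of bile acids made from cholesterol were higher in knockout liver. Cyp7a1, the rate-limiting enzyme of the classic pathway, rose from 61.9 ± 22.7 to 261 ± 16.4 CPM (log2 difference 2.13 ± 0.20, adjusted p = 5.00e-05). Cyp8b1, the sterol 12-alpha-hydroxylase needed for cholic acid, rose from 226 ± 27.4 to 742 ± 76.0 CPM (1.72 ± 0.12, adjusted p = 5.15e-06). Of 15 tested genes of bile acid synthesis and conjugation, 6 rose, 1 fell and 8 did not pass (7 and 1 adjusted over the list alone). Cyp7b1, of the alternative pathway, was at 182 ± 64.1 CPM in wild type and 340 ± 94.8 in knockout (0.93 ± 0.25, adjusted p = 0.0232; 0.60 without wild-type library 1), a call lost in 4 of the 6 fits without 1 library (highest adjusted p = 0.0707) and under robust variance moderation (adjusted p = 0.211). Scp2, the most abundant member that did not pass, had a log2 difference of −0.05 ± 0.12. The list passed camera (adjusted p = 0.0225), but the call did not hold with an estimated correlation (adjusted p = 0.564 with an estimated correlation) or in limma trend (adjusted p = 0.113). The number of members that rose was 2 without wild-type library 3, knockout library 1 or knockout library 2, and 3 without wild-type library 1 or knockout library 3.

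Among 12 tested bile acid and canalicular transporters, 3 rose, 3 fell and 6 did not pass (4 and 3 adjusted over the list alone). Slco1a1, an organic anion uptake transporter, fell from 702 ± 76.4 to 365 ± 37.9 CPM, and Slco1b2 from 1278 ± 38.4 to 910 ± 76.2 CPM. Abcb11, the bile salt export pump, had a log2 difference of 0.06 ± 0.11 (adjusted p = 0.768). Among 22 nuclear receptors, 4 rose, 4 fell and 14 did not pass (5 and 5 adjusted over the list alone), with Nr2f6 rising by 1.02 ± 0.15 and Nr1i3, the xenobiotic receptor CAR, falling by −0.82 ± 0.16 on the log2 scale. Nr1h4, which encodes FXR, had a log2 difference of 0.18 ± 0.10 (adjusted p = 0.247), and Hnf4a one of 0.14 ± 0.10 (adjusted p = 0.371). Nr5a2, encoding LRH-1, had −0.34 ± 0.11 (adjusted p = 0.0466), a call lost in each fit without 1 library (adjusted p up to 0.142). Neither list passed camera; without wild-type library 3, 0 transporters rose and 3 fell, and 1 receptor rose and 2 fell.

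Of 23 tested genes of cholesterol synthesis and uptake, 15 rose, 1 fell and 7 did not pass (17 and 1 adjusted over the list alone). Sqle, squalene epoxidase, rose from 55.3 ± 7.54 to 124.0 ± 12.4 CPM (log2 difference 1.16 ± 0.13, adjusted p = 0.000153). Insig1 had a log2 difference of 0.07 ± 0.13. The list passed camera (adjusted p = 1.83e-09), and the call did not hold with an estimated correlation (adjusted p = 0.509 with an estimated correlation).

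Of 27 tested genes of xenobiotic metabolism, 1 rose, 11 fell and 15 did not pass, and adjusted over the list alone 2 rose and 16 fell. Cyp2c29 fell from 1566 ± 150 to 646 ± 99.8 CPM (−1.28 ± 0.12, adjusted p = 5.00e-05), Ephx1, microsomal epoxide hydrolase, from 466 ± 58.5 to 247 ± 16.9 CPM, and Cyp2c50 from 750 ± 66.2 to 420 ± 29.0 CPM. Cyp2c29 and Cyp2c50 share a cluster of near-identical genes, so their separate values are uncertain. Cyp2e1 was at 6487 ± 769 CPM in wild type and 6150 ± 466 CPM in knockout and did not pass. Camera gave an adjusted p of 1.46e-07, and the call did not hold with an estimated correlation (adjusted p = 0.509 with an estimated correlation).

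Of 19 tested genes of one-carbon and homocysteine metabolism, 10 rose, 0 fell and 9 did not pass; without wild-type library 3, 5 rose. Adjusted over the list alone, 13 rose and 1 fell. Bhmt, which remethylates homocysteine with betaine, rose from 514 ± 95.8 to 1419 ± 77.4 CPM (1.48 ± 0.13, adjusted p = 2.20e-05). Cth, which makes cysteine from cystathionine, rose from 387 ± 41.4 to 933 ± 140 CPM (1.27 ± 0.12, adjusted p = 6.34e-05), and Dmgdh from 620 ± 81.4 to 1108 ± 39.0 CPM. Cbs had a log2 difference of −0.06 ± 0.10. Camera gave an adjusted p of 3.40e-06, and the call did not hold with an estimated correlation (adjusted p = 0.509 with an estimated correlation).

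Acute phase and inflammation genes were higher in knockout liver for 12 of 28 tested, lower for 0, and 16 did not pass. Adjusted over the list alone, 15 rose. The number that rose was 4 without wild-type library 3, 6 without knockout library 1 or 2, and 18 without knockout library 3. Orm2, an acute phase glycoprotein whose value is uncertain because of near-identical copies, rose from 7.02 ± 0.690 to 26.2 ± 7.33 CPM, and Itih3 from 699 ± 14.7 to 1078 ± 97.5 CPM. Hpx had a log2 difference of 0.08 ± 0.17. The list passed camera (adjusted p = 9.18e-06; adjusted p = 0.759 with an estimated correlation). Interferon response genes rose in 6 of 27 tested, with 0 lower and 21 not past the threshold (7 rose adjusted over the list alone). Bst2 rose from 64.1 ± 4.15 to 111 ± 17.7 CPM, Irf7 from 23.5 ± 1.29 to 41.6 ± 3.88 CPM and Tap1 from 15.7 ± 5.76 to 34.1 ± 4.30 CPM. Ifi27l1 had a log2 difference of 0.22 ± 0.14. This list also passed camera (adjusted p = 0.00121; adjusted p = 0.509 with an estimated correlation).

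Immediate early and heat shock genes rose in 3 of 13 tested, and 10 did not pass (5 rose adjusted over the list alone). The 3 were Junb, Dusp1 and Zfp36, with log2 differences of 2.04 ± 0.55, 0.97 ± 0.28 and 1.05 ± 0.32. Knockout library 2 was the highest for each, with Junb at 157 CPM against 51.8 and 29.1 CPM in the other knockout libraries. Their calls were lost under robust variance moderation (adjusted p = 0.246, 0.266 and 0.285), and each also in 3 or 4 of the fits without 1 library; Zfp36 was at 0.60 without knockout library 2. Hspa8 had a log2 difference of 0.02 ± 0.22. The list passed camera (adjusted p = 0.00729; adjusted p = 0.797 with an estimated correlation), and did not pass without wild-type library 1 (adjusted p = 0.0608). Its median log2 difference of 1.13 was 0.61 without knockout library 2 and 2.25 without knockout library 3, where 13 of 13 rose; without wild-type library 1 or 2, 0 rose by limma voom. Of 25 major secreted proteins, 6 rose, 2 fell and 17 did not pass (8 and 2 adjusted over the list alone), and 1 rose and 1 fell without wild-type library 3 or knockout library 1. C3, the central complement component, rose from 11571 ± 1000.5 to 19550 ± 1711 CPM, Plg by 0.39 ± 0.09 on the log2 scale, and Gc, the vitamin D-binding protein, fell by −0.43 ± 0.09. Alb had a log2 difference of 0.05 ± 0.12. The list passed camera (adjusted p = 0.0301; adjusted p = 0.797 with an estimated correlation), and did not pass without wild-type library 1, wild-type library 3 or knockout library 2 (adjusted p = 0.0988, 0.15 and 0.0598) or in limma trend (adjusted p = 0.113).

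Called lipid and glucose genes went in both directions, and their lists did not pass camera in the fit of all 6 libraries. In fatty acid synthesis 4 of 20 rose, 1 fell and 15 did not pass (5 and 1 adjusted over the list alone; 2 and 2 over all genes without wild-type library 3, 2 and 1 without knockout library 1), with Agpat2 rising from 95.9 ± 17.9 to 207 ± 4.84 CPM and Me1, malic enzyme, falling from 40.5 ± 4.97 to 16.9 ± 2.26 CPM. Srebf1 and Fasn had log2 differences of −0.08 ± 0.13 and 0.28 ± 0.17 (adjusted p = 0.729 and 0.277). Among 21 genes of fatty acid oxidation and PPARA targets, 1 rose, 8 fell and 12 did not pass (1 and 8 adjusted over the list alone; camera adjusted p = 0.101). This list passed camera, towards lower, with no low-count filter (adjusted p = 0.00443) and without wild-type library 3, knockout library 1 or knockout library 3 (adjusted p = 0.00322, 0.0194 and 0.00988), while the members that fell numbered 3 to 8 across the fits without 1 library. These calls used the preset correlation, and with an estimated correlation and all 6 libraries camera gave an adjusted p of 0.852. Decr1 fell from 229 ± 11.7 to 143 ± 11.3 CPM and Cyp4a10, of a cluster with near-identical copies, by −1.52 ± 0.24 on the log2 scale, a call lost under robust variance moderation (adjusted p = 0.0562). Among 24 genes of lipid uptake and lipoproteins, 2 rose, 4 fell and 18 did not pass (2 and 4 adjusted over the list alone); 1 to 2 rose and 4 to 5 fell across the fits without 1 library. Fabp1, the liver fatty acid-binding protein, fell from 3897 ± 507 to 1781 ± 234 CPM and Fabp2 from 54.4 ± 7.94 to 22.4 ± 2.94 CPM. In glucose and glycogen metabolism 4 of 20 rose, 6 fell and 10 did not pass (5 and 6 adjusted over the list alone; 2 and 2 over all genes without wild-type library 3). Fbp1, of gluconeogenesis, rose from 604 ± 109 to 1206 ± 70.0 CPM. Pck1 and Ppargc1a had log2 differences of 0.05 ± 0.10 and 0.21 ± 0.29 (adjusted p = 0.793 and 0.669).

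No marker list of another cell type passed camera with all 6 libraries. Without knockout library 1, Kupffer cell and macrophage markers and matrix and stellate markers passed towards higher (adjusted p = 0.00465 and 0.0119). Sinusoidal endothelial markers passed towards lower without knockout library 2 or 3 (adjusted p = 0.0481 and 0.0390). These calls used the preset correlation. With an estimated correlation and all 6 libraries, camera gave an adjusted p of 0.852 for the macrophage, the matrix and the endothelial list. Of 21 Kupffer cell and macrophage markers 3 rose, among them C1qa from 37.9 ± 3.89 to 62.5 ± 13.9 CPM, of 22 matrix and stellate markers 2 rose (Col4a1 and Col4a2), and of 19 sinusoidal endothelial markers 1 rose (Lyve1). With all 6 libraries, 0 members of these lists fell by limma voom (1 macrophage marker by limma trend), with 20 members at an unadjusted p under 0.05 in either direction; 2 endothelial markers fell without knockout library 2 or 3, and 1 matrix marker without knockout library 3. Higher macrophage, matrix and endothelial markers numbered 0, 0 and 0 without wild-type library 3, 1, 0 and 0 without wild-type library 2, 1, 2 and 0 without knockout library 2, 2, 3 and 2 without knockout library 1, and 2, 3 and 0 without knockout library 3. Calls of C1qa, Col4a1, Col4a2 and Lyve1 were lost without wild-type library 3 (highest adjusted p over the fits without 1 library 0.0813, 0.0947, 0.154 and 0.0855). Adjusted over the list alone the counts were also 3, 2 and 1. Cholangiocyte (7 tested), erythroid (7), lymphocyte (3), neutrophil (1) and fetal or tumour markers (6) had 0 calls with all 6 libraries by limma voom and by limma trend, with 1, 2, 0, 0 and 2 members at an unadjusted p under 0.05. In other fits, 1 cholangiocyte marker fell under robust variance moderation, 2 fetal or tumour markers rose with no low-count filter, and 1 or 2 erythroid markers rose without knockout library 1 or 2. The pancreatic and the adipose, muscle and gut lists had 1 tested gene each, Cela1, which rose by 0.97 ± 0.21, and Car3, which fell by −0.48 ± 0.12; both calls were lost without wild-type library 3. Pericentral hepatocyte markers had 4 higher, 1 lower and 13 not past the threshold, and periportal markers 3, 6 and 11 (5 and 1, and 3 and 7, adjusted over the list alone). Without wild-type library 3, 2 periportal markers were higher and 2 lower.

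Of the remaining lists, male-biased genes had 4 higher, 2 lower and 14 not past the threshold (7 and 2 adjusted over the list alone), with Cyp4a12a, uncertain for its near-identical copies, rising from 197 ± 65.7 to 435 ± 11.9 CPM. Female-biased genes had 1 lower of 4 tested, circadian genes 1 higher and 3 lower of 21, iron genes 4 higher and 1 lower of 16, endoplasmic reticulum stress and ATF4 targets 3 higher of 17, cell cycle genes 1 higher and 1 lower of 12, and ribosomal proteins 7 higher and 2 lower of 69. Adjusted over the list alone these were 0 and 1, 2 and 3, 7 and 2, 5 and 1, 1 and 1, and 6 and 1. Without wild-type library 3 the numbers higher and lower were 0 and 2 for circadian genes, 2 and 1 for iron genes, 1 and 0 for stress genes, 0 and 1 for cell cycle genes and 3 and 0 for ribosomal proteins. Without knockout library 3 there were 6 stress genes and 8 male-biased genes higher, and without knockout library 1 there were 2 male-biased genes higher. Circadian genes had 5 lower without wild-type library 1. Fmo2, the female-biased gene past the threshold (−0.69 ± 0.22, adjusted p = 0.0488), lost its call in 5 of the 6 fits without 1 library (adjusted p up to 0.143), with total counts or upper quartile scaling, and with no low-count filter. Male-biased genes passed camera towards higher without wild-type library 3 or knockout library 3 (adjusted p = 0.0413 and 0.0230). Endoplasmic reticulum stress genes did so with the replicate block, with no low-count filter and without wild-type library 2 or knockout library 3 (adjusted p = 0.0406, 0.0117, 0.00633 and 0.00107). These calls used the preset correlation, and with an estimated correlation and all 6 libraries camera gave the male-biased and stress lists adjusted p = 0.852 and 0.797. Hlf, a clock output factor, fell from 63.9 ± 4.21 to 32.0 ± 4.02 CPM. Slc40a1, the iron exporter ferroportin, fell from 152 ± 14.0 to 93.7 ± 9.98 CPM, and Slc39a14 rose from 203 ± 17.1 to 341 ± 31.9 CPM. Median and mean log2 differences had opposite signs for nuclear receptors (0.11 and −0.04), lipid uptake (0.05 and −0.09), female-biased (−0.18 and 0.12), cell cycle (0.01 and −0.16), matrix (−0.01 and 0.15) and pericentral genes (−0.04 and 0.07).

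**Figure D2:**
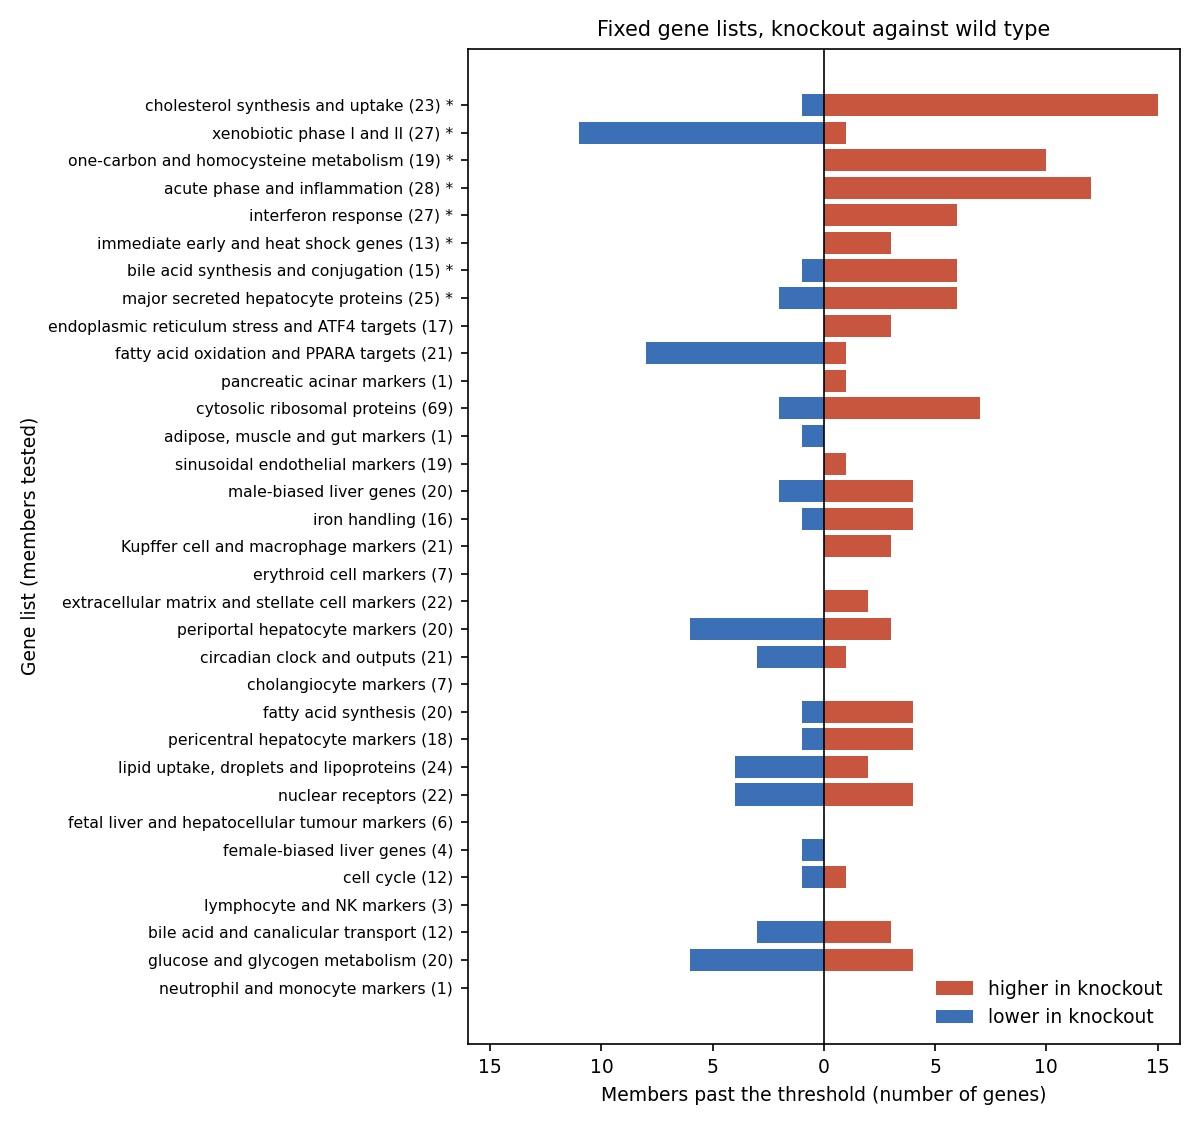
Number of members higher (right) and lower (left) in knockout among the 33 fixed lists, ordered by camera p, with the number tested in brackets and a star on the 8 lists past the threshold. Cholesterol synthesis and uptake has 15 members higher and 1 lower, and xenobiotic metabolism 1 higher and 11 lower.

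The share of genes past the threshold near Nr0b2 was set against the rest of the genome. Extl1 and C1qa, named above, lie within 10 Mb of Nr0b2 on chromosome 4, and Cyp4a10 and Cyp4a12a within 20 Mb. Within 10 Mb of Nr0b2, 42 of 217 tested genes passed the threshold (19.4%), against 1670 of 11576 elsewhere (14.4%). The odds ratio was 1.42 (95% interval 0.987 to 2.01; two-sided Fisher exact test, p = 0.0510). By the same Fisher exact test it passed in the 20 Mb window (odds ratio 1.35, p = 0.0291). Within 10 Mb it also passed without wild-type library 3 (1.86, p = 0.0132), knockout library 1 (1.77, p = 0.00556) or knockout library 2 (1.52, p = 0.0386, Fisher exact test), and it was 0.983 without knockout library 3.

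In the authors' deposited table, 1535 genes had an adjusted p under 0.05, 871 with a higher and 664 with a lower log2 ratio in knockout. Of 1466 such genes among those tested here, 1307 were also called by limma, each with the same sign. The other 159 were not called by limma, and 406 genes called by limma were not among the authors' calls. Both comparisons used the same 6 libraries, so their overlap is not independent support.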

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

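Limma trend, robust variance moderation and the fit without mitochondrially encoded genes were chosen after seeing the data; the other alternatives were planned. The planned edgeR quasi-likelihood test, its robust form, DESeq2 and tests on RPKM per sample were not run. Between the fits of all 6 libraries, genes past the threshold numbered 1466 to 1869. Leaving out 1 library gave 620 to 1566 genes, 340 to 846 higher and 280 to 797 lower; fewer samples were fitted. Genes lower in knockout fell furthest without wild-type library 3 (280), knockout library 1 (483), knockout library 2 (493) and wild-type library 2 (545).

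Nr0b2 stayed lower in every fit run, and lost its call with the replicate block (−0.79), total counts only (−0.81) and no low-count filter (−0.81); without 1 library it ranged from −1.06 to −0.66. The lists past the threshold numbered 6 to 12 across the fits without 1 library, 5 with fry and 0 with an estimated correlation. Camera sets a list against the other tested genes, while fry tests the list by itself, so their counts answer different questions. Fry passed the cholesterol, xenobiotic, one-carbon, bile acid synthesis and interferon lists (adjusted p = 0.0432, 0.0213, 0.0352, 0.0352 and 0.0432). Acute phase, immediate early and secreted protein lists did not pass fry (adjusted p = 0.203, 0.502 and 0.213). At the preset correlation the 5 lists passed camera in each fit without 1 library (highest adjusted p from 1.22e-08 for cholesterol to 0.0467 for bile acid synthesis). The acute phase list also passed camera in each of these fits (highest adjusted p = 0.000149), while the immediate early and secreted protein lists did not. The odds ratio near Nr0b2 passed the threshold with median-of-ratios factors (1.48), total counts (1.43), upper quartile scaling (1.46), robust moderation (1.44) and windows of 5 Mb (1.54) and 20 Mb (1.35), and ranged from 0.983 to 1.86 without 1 library, passing in 3 of these 6 fits. For these differences between fits, the cause was not tested.

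Same-numbered samples had deviations correlating at −0.0187, −0.0210 and −0.0244 over the tested genes, so no pairing common to most genes was seen. With so few samples this cannot exclude a shared litter, day or lane that acted on some genes. The replicate block called 1779 genes and 9 lists, the added one being endoplasmic reticulum stress and ATF4 targets (camera adjusted p = 0.0406). With the block, 16 acute phase genes, 6 immediate early and heat shock genes and 5 major secreted proteins rose, against 12, 3 and 6 without it.

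Of 173 genes the naming rule allows, 111 were called; 71 of these kept their call in every alternative run, 34 lost it without some library, and 0 changed sign, while 23 of the 62 not called did. Of 93 genes followed for the text, 53 of 78 called genes kept their call throughout. Genes that did not pass and changed sign without 1 library were Srebf1 (−0.22 to 0.0070), Pck1 (−0.015 to 0.11), Ppargc1a (−0.17 to 0.58), Abcb11 (−0.032 to 0.15), Scp2 (−0.14 to 0.072), Insig1 (−0.064 to 0.24), Cyp2e1 (−0.17 to 0.013), Hpx (−0.056 to 0.27), Cbs (−0.14 to 0.029), Hspa8 (−0.22 to 0.37) and Alb (−0.053 to 0.19). In simulated counts for the 11794 genes, 2-fold changes were recovered for 68.9% of genes below the median level of 18.1 CPM and 100% of those above it. These shares hold for independent counts with the same dispersion for every gene, so they do not give the recovery of real genes that vary more.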

Other observations

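Tests of substrain genes, of genes 2 to 20 Mb from Nr0b2, of windows along the genome, of wild-type library 1 and of the mitochondrial set were chosen after the results were seen; the test within 10 Mb of Nr0b2 and the count over splits were planned.

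Of 20 tested transcripts encoded by the mitochondrial genome, 10 fell, 0 rose and 10 did not pass, with a median log2 difference of −0.64 (camera p = 1.22e-06 at the preset correlation and p = 0.0623 with an estimated correlation, unadjusted). AY172335.7, which held most of the mitochondrial counts, went from 92758 to 58908 CPM, mt-Nd2 from 913 to 392 CPM and mt-Cytb from 1354 to 797 CPM. These genes were chosen after their values were seen. Mitochondrial transcripts carry no cap of the kind selected for, so their level also depends on how much uncapped RNA passed the selection, which was not measured.

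Some genes known to differ between C57BL/6 substrains differed between the groups. Nnt, which is truncated in C57BL/6J, rose from 55.0 ± 5.72 to 139.67 ± 5.94 CPM (log2 difference 1.35 ± 0.12, adjusted p = 2.20e-05), Wdfy1 rose by 1.59 ± 0.17, Nlrp12 rose from 2.89 to 6.91 CPM, and Entpd4 fell by −0.65 ± 0.16, while Ide did not pass (−0.13 ± 0.13). Of 5 tested genes on a list of 8 drawn up after Nnt had been noticed, 4 passed (one-sided Fisher exact test, p = 0.00196), and 3 of the other 4 did (p = 0.0109). Both tests counted calls in either direction and did not use the kind of difference known for each gene. Their p-values therefore do not tell whether the changes match those of a given substrain. A candidate explanation is a different substrain background of wild-type and knockout mice, which both carry the label C57BL6. An effect of SHP on these genes was not tested and stays open, and the design confounds both. Such a background difference, if present, would be confounded with the genotype for every other called gene and list as well.

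The 10 Mb around Nr0b2 held a somewhat higher share of calls, which missed the threshold. Genes 2 to 20 Mb from Nr0b2 were called in 58 of 308 cases against 1576 of 10999 off chromosome 4 (odds ratio 1.39, one-sided Fisher exact test, p = 0.0189), as a donor-strain segment around the targeted allele may give. The lower 95% bound of that ratio was 1.02, but the region was chosen after the 20 Mb window had been seen, and the bound stayed above 1 only without knockout library 1 or 2 (1.12 and 1.04). A donor segment and an effect on the immediate neighbours alone, where 10 of 59 genes within 2 Mb were called, therefore both stay open, by a rule requiring every fit without 1 library to pass that was set after the first outcome was seen (the fit of all 6 libraries alone had favoured the segment). Of 347 windows of 20 Mb on other chromosomes, 9.51% had an odds ratio at least that of the window centred on Nr0b2. The share was 7.95% of the 88 that do not overlap, and 10.8% of 369 in the set used at first, which held windows over this locus. An uneven density of calls therefore stays open too. This ranking covers the centred window only. Windows centred at 125, 130, 135 and 140 Mb of chromosome 4, which also span Nr0b2, had odds ratios of 1.05, 1.21, 1.47 and 1.71. The highest had 43 of 193 genes called, and its rank was not tested. Without knockout library 3 the ratio was 1.09 at 2 to 20 Mb and 0.983 within 10 Mb.

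Wild-type library 1 lay nearer the knockouts on the first principal component (−20.4 against −35.1 and −35.0, knockouts 20.7 to 38.9). Among 387 genes called at least 2-fold without it, it stood a median of 24.8% of the way (36.0% over the 272 of them lying towards the knockouts, the set used at first) to the knockouts, against 7.42% and 0.138% for wild-type libraries 2 and 3 treated alike, but knockout library 3 stood 32.0% of the way to wild type. Knockout RNA mixed in at that share would bring every gene to at least that share of its knockout level, yet of 5 genes nearly silent in the other wild types (under 5% of the knockout level) Meg3 stood at 1.75%, Asns at 3.27% and AC092752.1 at 1.07%, while Cish stood at 18.7% and Xirp1 at 25.6%. Pooled, the 5 gave an upper 95% Poisson limit of 4.87% (5.23% if each 2 counts are 1 pair; 2.23% from 2 genes under a 2% limit tried first), which covers counting error only and is set by the most abundant genes, so the low shares of Meg3, Asns and AC092752.1 are what argues against such a mix. Its total of 5798186 counts, not the lowest of the wild types, argues against depth, and differences between animals at collection may remain and were not tested. Knockout library 3 had the highest Nr0b2 level of the knockouts (10.4 CPM, against 6.64 and 7.09 CPM in knockout libraries 1 and 2). Whether wild-type RNA was mixed into it was not tested.

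The real split of the 6 libraries gave 1713 genes, and the highest of the other 9 splits gave 0 by limma voom and by limma trend, with up to 506 at an unadjusted p under 0.05 against 3606 in the real split. Only 1 of 10 splits gave as many, and 10 splits cannot give a share under 0.05. Each of the other 9 splits mixes the genotypes, so a genotype difference adds to the spread within its groups and lowers its count. Their 0 calls therefore do not measure how many genes would be called between groups that do not differ.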
